A study of Mus musculus with 4 samples.

How the data were processed

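Sorted TdTomato-positive, CD45-negative LLC cells from 2 WT and 2 PAD4-DN tumour samples were analysed. Per the labels' protocols, tumours were digested with collagenase and hyaluronidase, 100 ng of total RNA was used for a strand-specific poly-A library with 13 PCR cycles, and libraries were sequenced as 75-cycle single-end reads. Per the submitters' processing notes the tools and builds named were kallisto and GRCm39; the kallisto version, annotation release and command settings are not given in the sources used here. Per the file headers, the authors deposited one kallisto abundance table per sample with the length, effective length, estimated counts and TPM of 117486 transcripts. The estimated counts deposited by the authors are expected read counts that need not be whole and are not normalized. The TPM values deposited by the authors are scaled for effective length and sum to 1000000 in each library. The median gap between length and effective length over transcripts of at least 5000 bases was 223.9 bases in WT replicate 1, 239.4 in WT replicate 2, 236.8 in PAD4-DN replicate 1 and 237.4 in PAD4-DN replicate 2.

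Transcripts were matched to genes by identifier without version, using GENCODE release M21 for gene names and biotypes. That annotation is on an earlier build than the files, so no coordinates are given. Of the transcripts, 116408 matched a gene and 1078 did not; the unmatched ones held 0.493%, 0.491%, 0.483% and 0.486% of counts in WT replicates 1 and 2 and PAD4-DN replicates 1 and 2 and were left out. Estimated counts were summed over each of 35905 genes and rounded to whole numbers. Xist and Tsix, fixed as sex-linked genes, had no transcript in the files' set and were not analysed here. Kallisto divides reads between similar transcripts by an estimate, so values of near-identical gene copies are uncertain. PCR reads without molecular identifiers are not independent molecules, so limits from counts cover counting error only.

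The PAD4-DN libraries were compared with the WT libraries, without a replicate block, by edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr (13718 genes kept, 13019 of them protein-coding), the quasi-likelihood test and Benjamini-Hochberg adjustment at 0.05. Log2 fold changes are PAD4-DN minus WT, and CPM values use TMM-scaled library sizes. A set of 32 gene lists was fixed before the data were examined, together with the tests, the alternatives and the rule for named genes. The 26 lists of programs, quality and other cell types with at least 5 tested genes were tested two-sided with camera from limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation and with fry. The named genes are protein-coding: the 12 per direction with the largest change among genes past the threshold, with at least 5 mean CPM and no overlap of libraries, filled by smallest unadjusted p where fewer passed; the 3 members with the smallest p of each list; and all deiminases and sex-linked genes. All 24 of the first kind were filled by p, and not every list member named by the rule is printed.

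Alternatives were DESeq2 1.42.0 on the 21921 genes with at least 1 count, with its own independent filtering, limma-voom, DESeq2 size factors in edgeR, no low-count filter, a mean of at least 5 CPM, limma-trend on log2(TPM + 1) with a mean TPM of at least 1, effective length offsets, a replicate block, protein-coding genes only, a false discovery rate of 0.1 and each library left out in turn. DESeq2 on the 13718 genes kept by filterByExpr was added after the data were seen. The tests were tried on 5 sets of simulated counts for the 13718 genes of this comparison, drawn from the real means, library sizes and dispersions, with 200 genes changed per set. edgeR called 2.8% of genes changed by 1.5-fold, 30.0% at 2-fold, 61.6% at 3-fold and 65.6% at 4-fold, all with the right sign, and 74 unchanged genes over the 5 sets. DESeq2 called 11.6%, 45.2%, 69.6% and 74.4%, with 182 unchanged genes. For both tools unchanged genes made up a larger share of the calls than the threshold of 0.05 allows. The simulated sets hold no pattern shared by many genes, such as the one that crossed the genotypes in the real libraries. These gene rates may therefore not carry over to the real data, where edgeR gave 2.65% of genes an unadjusted p under 0.05. With 1 list shifted by −0.25 on the log2 scale, camera called it in 4 of 5 simulations at the preset correlation and in 0 of 5 with an estimated correlation. Over the same simulations it also called 5 of 125 unshifted lists at the preset correlation and 0 with an estimated one. Genes were drawn independently, so these rates leave out correlation between the members of a list, estimated at 0.945 for type I interferon genes. With an estimated correlation even the shifted list was never called, so a lack of calls there is little evidence against a shift. Each group had 2 libraries, and the median standard error of a log2 fold change was 0.20.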

Results

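Gene expression was measured by poly-A RNA sequencing in Lewis lung carcinoma (LLC) cells, a mouse lung cancer line of C57BL/6 origin, recovered from subcutaneous flank tumours 4 weeks after implantation. The cancer cells carried TdTomato, and cells positive for TdTomato and negative for the leukocyte antigen CD45 were sorted from each tumour sample. The 4 libraries formed 2 groups of 2. All hosts carried floxed Padi4 alleles. WT hosts had no Cre, and PAD4-DN hosts carried Mrp8Cre, a driver active in neutrophils, which deletes the floxed gene there. The libraries held 23414984 and 25327974 estimated counts in WT replicates 1 and 2, and 20036322 and 24142484 in PAD4-DN replicates 1 and 2. Nothing in the sources used here states that the replicates came from separate animals or tumours, so p-values measure only the spread between these libraries.

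Padi4 encodes peptidylarginine deiminase 4, an enzyme that citrullinates histones and takes part in the release of neutrophil extracellular traps. In the sorted cancer cells Padi4 had 0 and 2 counts in the WT libraries and 6 and 0 counts in the PAD4-DN libraries, too few to be tested. A count of 0 allows up to 3 counts, or 0.128 CPM (counts scaled to a library of 1000000) in WT replicate 1 and 0.124 CPM in PAD4-DN replicate 2, for counting error only. The deletion was made in host neutrophils and not in the sorted cells, so these counts check neither the deletion nor the labels. Padi2 was the only deiminase abundant enough to test, at 8.40 and 5.51 CPM in WT and 3.32 and 8.17 CPM in PAD4-DN. Padi1, Padi3 and Padi6 had at most 4 counts in any library. The Y-linked genes were low, with Kdm5d at 1.58 and 1.55 CPM in WT and 1.90 and 2.10 CPM in PAD4-DN, Uty at 7.74 and 1.11 CPM against 11.6 and 3.61 CPM, and Ddx3y at 0.879 and 0.357 CPM against 1.27 and 0.503 CPM. Eif2s3y had at most 8 counts in any library.

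The comparison asked whether the transcriptome of primary tumour cells differs when the host's neutrophils lack Padi4. No gene passed a false discovery rate of 0.05 by edgeR's quasi-likelihood test after the low-count filter. Eed and Ints9 were called by DESeq2, with and without that filter, and by edgeR without it. In simulations unchanged genes made up a larger share of the calls than the threshold allows, for DESeq2 and for edgeR. The genes with the smallest p-values by edgeR are given here by their values. Eed, a core subunit of a Polycomb repressive complex, was at 4.54 ± 1.04 CPM in WT and 19.0 ± 0.0581 CPM in PAD4-DN (mean ± SD, n = 2 each), a log2 fold change of 2.06 (SE 0.23). Ints9, an Integrator complex subunit, was at 10.6 ± 0.849 CPM in WT and 24.5 ± 1.09 CPM in PAD4-DN. Bax, a pro-apoptotic p53 target, was at 45.6 ± 2.55 CPM in WT and 30.7 ± 0.854 CPM in PAD4-DN, and Slc7a5, a large neutral amino acid transporter, was at 132 ± 6.68 CPM and 95.2 ± 0.162 CPM. The secreted netrin Ntn4 was at 16.8 ± 2.43 CPM in WT and 7.95 ± 1.38 CPM in PAD4-DN, a log2 fold change of −1.08 (SE 0.22).

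With edgeR's quasi-likelihood test, 0 of 13718 genes passed after Benjamini-Hochberg adjustment, and the smallest adjusted p was 0.988. By the same test 364 genes (2.65%) had an unadjusted p under 0.05, of which 169 were higher and 195 lower in PAD4-DN. On the same 13718 genes limma-voom also gave 0 genes, with 362 at an unadjusted p under 0.05, and DESeq2, in a fit added after the data were seen, gave 11 genes, 6 higher and 5 lower, with 364. Without the low-count filter, on 21921 genes, DESeq2 gave 10 genes (5 higher, 5 lower) with 367 at an unadjusted p under 0.05, and edgeR gave 10 (4 higher, 6 lower) with 737. These last fits shared 8 genes: Eed, Ints9, Gm10800 and, outside the rule for named genes, AC129217.1, Gm10288, Gm1821, Gm45234 and Gm7887. Arrdc3 was called by DESeq2 in both of its fits and Klf10 in the filtered one. The libraries of the 2 genotypes did not overlap for 4501 genes (32.8%), against 33.3% given by chance. An exact permutation test of 2 libraries against 2 cannot give a two-sided p below 0.333.

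By the rule for named genes, 12 genes above WT and 12 below WT were taken by smallest unadjusted p among protein-coding genes of at least 5 CPM without overlap. Besides Eed and Ints9, those above WT were Arrdc3, an arrestin-domain gene (52.2 ± 5.15 against 89.9 ± 1.89 CPM), Klf10, a transcription factor induced by TGF-beta (462 ± 28.0 against 676 ± 6.80 CPM), Ptprk, Colec12, Medag, Kansl1l, Zbtb20, Plscr4, Dnal1 and Vmn2r53. The log2 fold changes of the last 8 lay between 0.47 for Medag and 0.76 for Ptprk. Below WT, besides Bax, Slc7a5 and Ntn4, were Gm10800, Syngr2, Etv4, Plxna4, 2900026A02Rik, Tmc6, Aen, Rgs12 and Tpst2. The ETS factor Etv4 was at 46.1 ± 0.453 CPM in WT and 31.9 ± 1.30 CPM in PAD4-DN. The predicted gene Gm10800 was at 50.9 and 14.8 CPM in the WT libraries and at 2.15 and 2.31 CPM in the PAD4-DN libraries. Vmn2r53 belongs to a large family of vomeronasal receptors, and reads shared within the family make its value uncertain. In counts not scaled for library size, the Eed difference lay mostly in 1 of its 10 transcripts. That transcript had 2.39 and 1.98 estimated counts in WT and 265 and 248 in PAD4-DN. The other Eed transcripts together had 118 and 94.4 counts in WT and 124 and 205 in PAD4-DN, also higher in both PAD4-DN libraries. Such all-or-none transcripts, with at least 100 counts in both libraries of a pair and under 10 in both others, numbered 19 by genotype, against 35 and 33 for the other splits of the libraries into pairs.

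**Figure D1:**
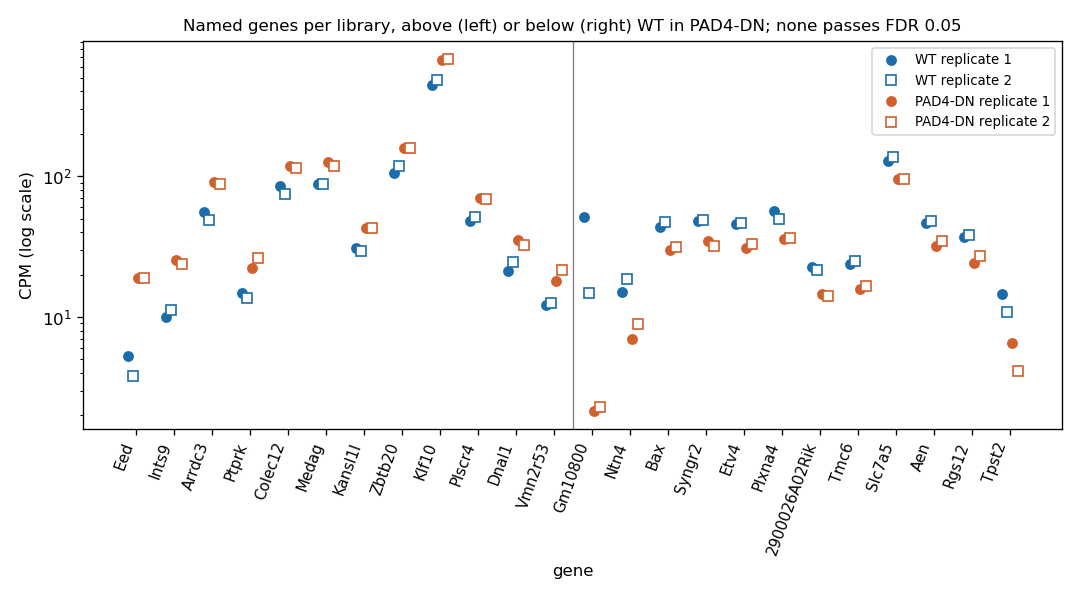
Level of the 24 named genes in each library, in CPM on a log scale; points are single libraries, blue for WT and orange for PAD4-DN. Klf10 is the most abundant of them and Gm10800 differs most, with 50.9 and 14.8 CPM in WT against 2.15 and 2.31 CPM in PAD4-DN.

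Interferon-response genes were lower in PAD4-DN as lists, with limma's camera at a preset correlation of 0.01 (adjusted p = 1.25e-15 for type I interferon and 1.25e-12 for interferon-gamma). Both lists had adjusted p = 0.847 with an estimated correlation. The type I interferon response list had a median log2 fold change of −1.10 over its 32 members, 31 of them negative. The interferon-gamma and class I antigen presentation list had a median of −0.65 with all 32 negative. Both PAD4-DN libraries lay below both WT libraries for 3 and 6 of the 32 members of each list in this order, against 16.7% given by chance. Zbp1, a sensor of Z-form nucleic acid, was at 10.6 and 19.2 CPM in WT and 5.17 and 6.50 CPM in PAD4-DN. Cmpk2 was at 4.04 and 22.4 CPM against 4.34 and 1.43 CPM, and Oasl1 at 1.63 and 5.31 CPM against 1.51 and 0.713 CPM. The class I light chain B2m was at 615 and 828 CPM in WT and 476 and 517 CPM in PAD4-DN, the class I heavy chain H2-D1 at 516 and 722 CPM against 476 and 360 CPM, and the proteasome activator Psme1 at 89.1 and 111 CPM against 82.1 and 74.7 CPM. No member of either list passed over all genes by edgeR, and 0 passed adjusted over the list alone. On log2(TPM + 1) with limma-trend the type I median was −0.68 (camera adjusted p = 1.13e-09). Both lower medians rested on WT replicate 2, without which the medians were 0.14 and −0.04. They were −1.74 and −1.01 without WT replicate 1, −1.70 and −1.12 without PAD4-DN replicate 1, and −0.78 and −0.43 without PAD4-DN replicate 2. Fibroblast markers were also above the mean of the libraries in WT replicate 2, by a median of 0.89 on the log2 scale, and by 0.84 in PAD4-DN replicate 1, where type I interferon genes were at −0.16.

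Genes of the p53 target, unfolded protein and integrated stress response, oxidative phosphorylation and ribosomal protein lists were lower in PAD4-DN by smaller amounts, with camera at the preset correlation. With an estimated correlation, adjusted p was 0.754 for p53 targets, 0.754 for the unfolded protein and integrated stress response, 0.754 for oxidative phosphorylation and 0.847 for ribosomal proteins. The p53 target list had a median log2 fold change of −0.25, with 17 of 21 members negative and 11 below both WT libraries in both PAD4-DN libraries. Besides Bax, its members with the smallest p were the apoptosis-enhancing nuclease Aen, at 46.7 and 48.0 CPM in WT and 32.1 and 34.4 CPM in PAD4-DN, and the stress-induced Sesn2, at 29.6 and 30.5 CPM against 20.2 and 22.3 CPM. The unfolded protein and integrated stress response list had a median of −0.15, with 22 of 30 members negative. It included Slc7a5, Sesn2 and the mitochondrial serine hydroxymethyltransferase Shmt2, which was at 93.8 and 115 CPM in WT and 71.0 and 75.2 CPM in PAD4-DN. Nuclear genes of oxidative phosphorylation had a median of −0.13, with 40 of 43 members negative, among them Uqcrq (23.9 and 19.3 against 17.0 and 14.0 CPM), Cox8a and Cox6a1. Ribosomal protein genes had a median of −0.21, with 46 of 48 negative, among them Rps2 (2052 and 1938 against 1573 and 1556 CPM) and Rpl27.

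With camera at the preset correlation, adjusted p was 1.18e-06 for p53 targets, 0.00109 for the unfolded protein and integrated stress response, 1.84e-06 for oxidative phosphorylation and 5.25e-10 for ribosomal proteins. With an estimated correlation these were 0.754, 0.754, 0.754 and 0.847. On log2(TPM + 1) with limma-trend the medians were smaller, at −0.15, −0.05, −0.07 and −0.12 in the same order, with camera adjusted p = 0.00132, 0.0443, 0.000658 and 3.33e-08, while the median over all genes shared by both fits was 0.06 there and −0.01 by edgeR. No member of these 4 lists passed by edgeR, over all genes or adjusted over the list alone. The median for p53 targets was −0.40 without PAD4-DN replicate 2. That for ribosomal proteins was −0.07 without WT replicate 1 and −0.31 without WT replicate 2.

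Inflammatory cytokine, immediate early and heat shock, and neutrophil genes were higher in PAD4-DN as lists, with camera at the preset correlation (adjusted p = 0.00755, 0.000452 and 0.0216 in this order). PAD4-DN replicate 1 was the highest library for each list, while PAD4-DN replicate 2 lay below 1 WT library. Relative to the mean of the libraries, it was at −0.036, −0.216 and −0.558 on the log2 scale in the same order. WT replicate 1 was at 0.006 for the first and 0.518 for the third, and WT replicate 2 at 0.016 for the second. With an estimated correlation, adjusted p was 0.754, 0.847 and 0.847. The NF-kB and inflammatory cytokine list had a median log2 fold change of 0.24, with 19 of 28 members positive. In it the chemokine Ccl7 was at 50.3 and 43.3 CPM in WT and 90.9 and 59.4 CPM in PAD4-DN, the neutrophil chemoattractant Cxcl1 at 86.9 and 125 CPM against 239 and 133 CPM, and Nfkb2 in the other direction at 85.5 and 92.6 CPM against 71.4 and 74.2 CPM. Immediate early and heat shock genes had a median of 0.41, with 23 of 26 positive, among them Klf6 (325 and 440 against 624 and 444 CPM) and Hspa1b (47.3 and 48.6 against 79.2 and 48.6 CPM). Neutrophil markers had a median of 0.65 over 8 tested members, all positive, at low levels, such as Cxcr2 at 2.42 and 1.71 CPM in WT and 3.61 and 3.94 CPM in PAD4-DN and Mmp8 at 0.396 and 0.159 CPM against 1.37 and 0.629 CPM. The NF-kB and neutrophil calls ended with limma-voom (adjusted p = 0.0750 and 0.0647) and with limma-trend on log2(TPM + 1) (adjusted p = 0.0524 and 0.340). No member passed by edgeR, over all genes or adjusted over the list alone. Without PAD4-DN replicate 1 the medians were 0.11, −0.16 and −1.10. Without WT replicate 1 they were 0.56, 0.16 and 2.20, and without WT replicate 2 they were 0.04, 0.63 and 0.19. Without PAD4-DN replicate 2 they were 0.35, 0.74 and 1.11. PAD4-DN replicate 1 also had the highest macrophage markers, by a median of 1.19 on the log2 scale above the mean of the libraries, and the highest erythroid and platelet markers, by 2.22.

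**Figure D2:**
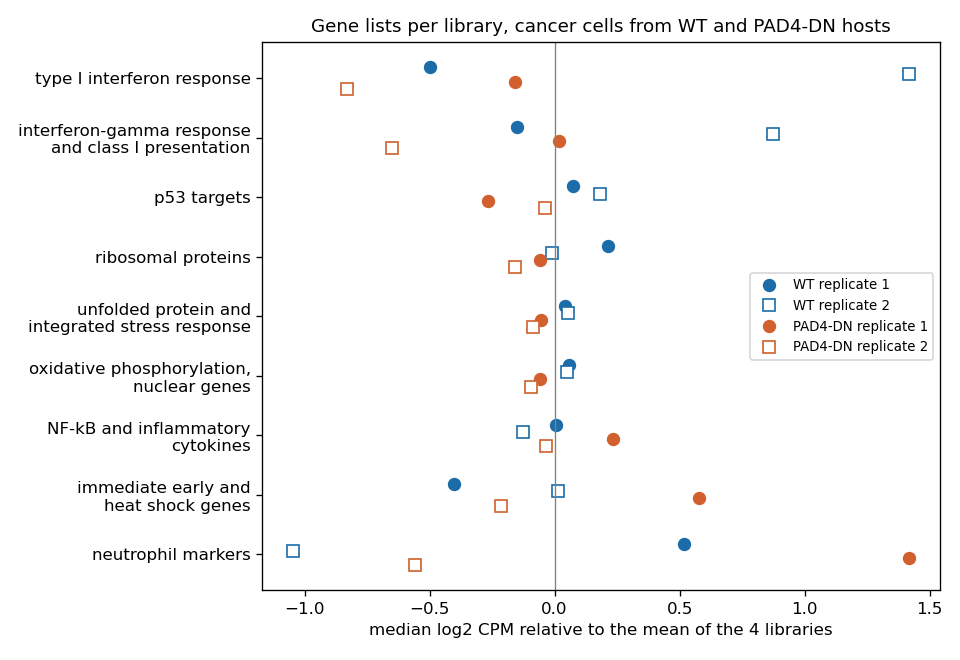
Median log2 CPM of the members of each of the 9 lists that passed with the preset correlation, relative to the mean of the 4 libraries; points are single libraries, blue for WT and orange for PAD4-DN. WT replicate 2 lies apart for type I interferon genes at 1.42, and PAD4-DN replicate 1 for neutrophil markers at 1.42.

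The other 8 program lists did not pass with camera, and no member passed by edgeR, over all genes or adjusted over the list alone. Their median log2 fold changes were −0.02 for hypoxia and glycolysis, 0.02 for cell cycle and proliferation, 0.13 for epithelial-mesenchymal plasticity, −0.04 for collagens and their processing, −0.05 for the NRF2 oxidative stress response, 0.00 for cholesterol biosynthesis, −0.03 for angiogenic factors and 0.05 for coagulation and protease genes. On log2(TPM + 1) the medians for hypoxia, collagens and angiogenic factors were 0.07, 0.02 and 0.09, and that for angiogenic factors was 0.01 with limma-voom. The cell cycle members with the smallest p were Mcm3 (135 and 142 against 108 and 115 CPM), Mcm2 and Mcm5, and 5 of the 33 members were below both WT libraries in both PAD4-DN libraries, against 16.7% given by chance. Tissue factor F3, the initiator of coagulation, was at 45.1 and 32.3 CPM in WT and 57.9 and 51.3 CPM in PAD4-DN, and its inhibitor Tfpi at 116 and 104 CPM against 142 and 144 CPM. Vegfb was at 31.5 and 35.3 CPM in WT and 25.0 and 26.4 CPM in PAD4-DN, the lactate exporter Slc16a3 at 40.4 and 29.9 CPM against 25.7 and 24.2 CPM, and the collagen-processing enzyme Plod3 at 102 and 99.7 CPM against 83.8 and 81.3 CPM. Mitochondrially encoded genes had a median of −0.14 and did not pass. For angiogenic factors the mean was 0.11 and the test pointed up, against a negative median, and for cholesterol biosynthesis the mean was 0.01 and the test pointed down. With an estimated correlation a lack of calls is little evidence against a shift, given so few libraries. Medians of several of these lists moved once 1 library was left out, in directions that depended on the library. The median for coagulation and protease genes ran from −0.12 to 0.31, and that for epithelial-mesenchymal plasticity from −0.07 to 0.16. These fits keep 1 library in a group, so only medians are given for them. Without WT replicate 1 the median was 0.25 for hypoxia, −0.17 for cell cycle and −0.20 for collagens. It was 0.18 for angiogenic factors and −0.28 for mitochondrially encoded genes. Without WT replicate 2 it was −0.34 for hypoxia, 0.21 for cell cycle and 0.16 for epithelial-mesenchymal plasticity. It was 0.29 for collagens and −0.23 for the NRF2 response. Without PAD4-DN replicate 1 it was −0.48 for collagens and 0.31 for cholesterol biosynthesis. Without PAD4-DN replicate 2 it was 0.23 for collagens, −0.42 for cholesterol biosynthesis and 0.08 for epithelial-mesenchymal plasticity. It was −0.21 for the NRF2 response and −0.19 for mitochondrially encoded genes.

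Markers of other cell types were compared in the same way. Of the 9 such lists tested, only neutrophil markers passed with camera at the preset correlation. With an estimated correlation their adjusted p was 0.847, and with fry it was 0.992. Median log2 fold changes were 0.34 for macrophages and monocytes, 0.09 for B cells and dendritic cells, 0.23 for pan-leukocyte genes, −0.15 for endothelium, 0.03 for fibroblasts, −0.14 for pericytes and smooth muscle, 0.45 for skeletal muscle and 1.38 for erythroid cells and platelets. No member passed by edgeR, over all genes or adjusted over the list alone. The test pointed down for macrophage and pan-leukocyte genes and up for pericyte genes, against the sign of their medians, and the mean for pericytes was −0.02. With limma-voom the median was −0.41 for macrophages and monocytes, −0.23 for pan-leukocyte genes, −0.49 for endothelium and 0.53 for erythroid cells and platelets, and on log2(TPM + 1) it was −0.11, 0.03, −0.01 and 0.69. Fits with a library left out keep 1 library in a group, so only medians are given for them. Without PAD4-DN replicate 1 the median was −1.71 for macrophages and monocytes, −1.34 for pan-leukocyte genes and −1.02 for endothelium. It was −1.12 for erythroid cells and platelets and −1.41 for fibroblasts. Without PAD4-DN replicate 2 it was 1.07 for macrophages and monocytes and 0.96 for pan-leukocyte genes. It was 0.55 for fibroblasts and 2.28 for erythroid cells and platelets. It was 1.45 for fibroblasts without WT replicate 2 and 2.53 for erythroid cells and platelets without WT replicate 1. Over the libraries left out in turn, medians ran from −1.02 to 0.50 for endothelium and from −1.02 to 0.45 for pericytes and smooth muscle. They ran from −0.11 to 0.58 for skeletal muscle and from −0.02 to 0.40 for B cells and dendritic cells. With an estimated correlation a lack of calls is little evidence against a shift, given so few libraries. The VEGF receptor Flt1 was at 28.9 and 29.1 CPM in WT and 21.8 and 18.9 CPM in PAD4-DN, the dermal matrix gene Dpt at 135 and 154 CPM against 255 and 180 CPM, the integrin chain Itgb2 at 70.9 and 42.8 CPM against 72.0 and 73.3 CPM, and the immunoglobulin gene Ighm at 0.615 and 0.555 CPM against 1.51 and 1.68 CPM. Lists for T and NK cells, adipocytes and keratinocytes had fewer than 5 tested members. Of the epithelial and lung lineage genes, 6 were tested and none passed, over all genes or adjusted over the list alone.

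The libraries did not group by genotype. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.969 between the WT libraries and 0.965 between the PAD4-DN libraries. It was 0.981 between WT replicate 1 and PAD4-DN replicate 2, and 0.978 between WT replicate 2 and PAD4-DN replicate 1. The first principal component, with 52.8% of the variance, separated those pairs from each other.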

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

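All settings were fixed before the data were examined except the crossed pairing, DESeq2 on filtered genes and the estimated correlation with a replicate left out. The count of genes past the threshold stayed at 0 with DESeq2 size factors, limma-voom, a mean of at least 5 CPM, limma-trend on TPM, effective length offsets, protein-coding genes only and a false discovery rate of 0.1. It was 10 with no low-count filter (4 higher, 6 lower), 11 with DESeq2 on the filtered genes (6 higher, 5 lower) and 10 with DESeq2 as planned, which changes both the test and the filter (5 higher, 5 lower), so either change alone gave calls; the cause was not tested. Leaving out each replicate gave 0 to 2 genes, 0 to 1 higher and 0 to 2 lower: Gm10800 and Rpl15-ps3 without WT replicate 2 and Gm28661 without PAD4-DN replicate 1 (genes outside the rule are named after their values were seen), the lone library being assumed to vary like the other group. With a replicate block 0 genes passed, and 0 passed with the crossed replicate block, chosen after seeing the data because deviations of same-numbered libraries correlated at −0.34. Of the lists, 9 passed with the replicate block and 7 to 12 under the other tools, filters and scalings, 12 to 18 with a replicate left out (6 to 9 of them among the 9), 0 with an estimated correlation, 0 with that and any replicate left out, and 0 with fry; each of the 9 still called kept its direction. The estimated correlation could rarely call a list with so few libraries, so its counts of 0 are little evidence against a shift. The NF-kB and neutrophil calls ended with limma-voom and with limma-trend on TPM. The neutrophil list had too few members to be tested at a mean of 5 CPM. DESeq2 without the filter added hypoxia (adjusted p = 0.0437), the NRF2 response (0.0429) and mitochondrially encoded genes (0.00397), and on the filtered genes it added the last alone (0.0231). With the replicate block the median was −0.26 for macrophage and −0.17 for pan-leukocyte markers, against 0.34 and 0.23 without it; neither passed. The mean r within genotypes minus that between was −0.007, against −0.004 on log2(TPM + 1) and −0.10 over the 500 most variable genes, a selection that favours genes that differ between libraries. Leaving out replicates moved the median of type I interferon genes from −1.74 to 0.14, of neutrophil markers from −1.10 to 2.20, of immediate early genes from −0.16 to 0.74, of erythroid and platelet markers from −1.12 to 2.53, of fibroblast markers from −1.41 to 1.45, of macrophage markers from −1.71 to 1.07 and of pan-leukocyte markers from −1.34 to 0.96. Of 67 named genes, 916 of 929 values kept their sign, and 13 values of 7 genes reversed, all with a replicate left out: Padi2 (−1.07 to 0.22), Col1a1 (−4.02 to 4.38), Col1a2 (−5.68 to 8.05), Uty (−0.30 to 2.76), Ddx3y (−0.30 to 1.29), Mmp12 (−0.93 to 1.73) and Fos (−0.20 to 2.33). Genes named for a small p without overlap of libraries could hardly reverse, so the kept signs are little evidence of stability. Low levels limit the pan-leukocyte markers, whose median lay between 0.419 and 2.59 CPM over the libraries.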

Other observations

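Genes named in this part outside the fixed lists' top members were chosen after their values were seen. Col1a1, the main chain of type I collagen, was at 16.0 and 16.9 CPM in WT replicate 1 and PAD4-DN replicate 2 and at 531 and 652 CPM in WT replicate 2 and PAD4-DN replicate 1. Its partner Col1a2 was at 0.881 and 3.94 CPM in the first pair and 404 and 467 CPM in the second. The immediate early gene Fos was at 114 and 286 CPM against 540 and 866 CPM, and the macrophage metalloelastase Mmp12 at 576 and 667 CPM against 128 and 187 CPM. Of the 3 ways to split the 4 libraries into pairs, edgeR called 0 genes by genotype (364 at an unadjusted p under 0.05), 108 genes for this split (970) and 0 genes for the remaining one (551); DESeq2, run only by genotype, called 11 of the same 13718 genes. The 108 genes and the correlations between libraries describe the same structure, which crosses the genotypes, and are not independent evidence of it.

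The tests on this split and on interferon genes were chosen after the results were seen, and the length and GC tests before. A candidate explanation for the split is host fibroblasts in WT replicate 2 and PAD4-DN replicate 1, although the sort required TdTomato. Of all 15 tested fibroblast markers, 11 were higher in both than in both other libraries (73.3%, exact binomial interval 44.9% to 92.2%). That share did not decide by the bounds set, and markers of 1 cell type are not independent. Chance gives 16.7% for a pair named beforehand, but this pair was chosen from these data, so that share does not apply to it. Dcn (981 and 770 CPM in WT, 981 and 1045 CPM in PAD4-DN), Lum, Fap and Dpt were not higher in both. The summed markers were at 1861 and 1846 CPM in WT and 2095 and 2208 CPM in PAD4-DN. That sum follows Dcn and Lum, which were also high in WT replicate 1 and PAD4-DN replicate 2. There Mfap5 was at 0.0440 and 0.126 CPM. The sum therefore does not decide either, and fibroblasts stay open. Lower sort purity stays open too, since the CD45 gate removes leukocytes at any purity; earlier tests of both, on markers picked for low levels in the other libraries, were void and were dropped. An exchange of labels between a WT and a PAD4-DN library stays open and was not tested, because the deletion was made in host neutrophils and Padi4 counts of the sorted cells check no label.

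The lower interferon lists followed one library, WT replicate 2, without which the type I median was 0.14. Leukocytes in that library, which the CD45 gate would remove, stay open by their markers. The markers' summed level was −61.9 CPM relative to the other libraries (interval −136 to −12.0), while interferon genes were 673 CPM higher. A first test, the markers' median log2 ratio, gave 0.24, did not decide and was replaced by the sum. By the bounds set, which were chosen after the values were seen, the sum spoke against leukocytes. The sum follows a few abundant markers, however, so it does not decide. In PAD4-DN replicate 2 pan-leukocyte markers had a median of 0.419 CPM and a sum of 123 CPM. In WT replicate 2 these were 1.35 and 90.2 CPM. Stromal cells in that library stay open: the excess of interferon genes in PAD4-DN replicate 1 was a share of 0.27 (0.16 to 0.34) of that in WT replicate 2, but that value is from 1 library and assumes that stromal cells of both carry interferon genes alike. An interferon response of the cancer cells in that library stays open and was not tested, and so does the host genotype.

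The lower p53 targets and ribosomal proteins were tested for a transcript length or GC content trend. After its removal the p53 median was −0.32 (−0.40 to −0.17), against −0.25 before, so the trend does not account for it. The ribosomal median went from −0.21 to −0.13 (−0.18 to −0.11), so part may follow the trend and the rest cannot be told apart from it by the bounds set. An effect of the host genotype stays open for both, as a hypothesis.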
